A study of Mus musculus with 4 samples.

How the data were processed

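RNA from 4 samples of PPS-ICBR, a mouse prostate cancer cell line, was sequenced. The line carries a knockout of Pten, Trp53 and Smad4 and is described in the labels as resistant to castration and to immunotherapy. A group of 2 samples was kept in DMEM culture medium (untreated) and a group of 2 received 3 mM beta-hydroxybutyrate (BHB), a ketone body, for 18 h. Total RNA was extracted with a Zymo Research miniprep kit and sequenced at GeneWiz, per the labels' protocols. The aligner was STAR, per the submitters' processing notes. Its version, the genome build, the annotation, the counting program and the use of strand are not given in the sources used here, so no coordinates are printed and reads of overlapping or antisense genes cannot be told apart.

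Each deposited table lists a RefSeq transcript identifier, a gene symbol, a read count, an FPKM and a TPM, per the file headers. The deposited count column held whole numbers and was taken as raw counts. The deposited FPKM column (fragments per kilobase of transcript, scaled to the column total) was the count divided by transcript length and by the total of the count column, since the lengths recovered this way were whole to within 0.01 bases for 100% of the 25518 rows with a count. The deposited TPM column, scaled for transcript length, summed to 1000000. FPKM and TPM entered no test.

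The tables had 33984 transcript rows for 24063 gene symbols. Of the 3214 symbols with several rows at a mean count of 50 or more, 72.3% had a lowest row within 5 percent of the highest, so the rows of a gene largely repeat the same reads. Each gene was therefore represented by its transcript row with the highest mean count over all 4 samples. This choice was made after the data were examined. Summed rows and separate rows were run as alternatives. The gene totals were 26984713 and 24750740 counts for untreated replicates 1 and 2, and 27872163 and 27942749 for BHB replicates 1 and 2. No mitochondrially encoded mRNA was listed.

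The comparison used the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr at a minimum count of 10 and treatment as the only term. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the 12960 genes tested. A gene was called at an adjusted p below 0.05. Standard errors of log2 fold changes were derived from the F statistic. CPM values (counts scaled to a library of 1000000) were computed with TMM-scaled library sizes and are given as mean ± SD. The replicate numbers come from the sample titles, where they follow the words Cell Line and are the same in both groups. Nothing says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. With 2 samples per group the fit has 2 residual degrees of freedom, and edgeR borrows information across genes.

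Before the data were examined, 36 gene lists, the test and the rule for named genes were fixed. Lists with at least 5 measured members (33 of 36) were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and the self-contained fry test were run beside it. With an estimated correlation camera uses the 2 residual degrees of freedom, so a list could hardly pass whatever its correlation. Its lowest p over the lists was 0.0507 (adjusted p = 0.777). For the prostate markers, with an estimated correlation of -0.0661, the camera p went from 0.000343 to 0.0647. A call lost under this setting is therefore not by itself an effect of correlated genes. The rule named the 12 largest rises and 12 largest falls among called genes with a mean count of at least 50, a symbol that is not a predicted gene or pseudogene, and both BHB samples on the same side of both untreated samples. It also named 19 genes fixed by symbol, up to 4 members with the smallest p of each list described, and the 5 genes with the smallest p overall. Other called list members, and the genes said to be chosen later, were named after their values were seen.

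Transcript length came from the FPKM values, and GC content and exon number from GENCODE vM21 transcripts, matched by accession or symbol for 99.4% of the tested genes. For a GC and length correction, the trend of each library's log2 CPM on both was fitted by loess (span 0.4) and entered as an offset.

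The procedure was tested on simulated data drawn from the means, dispersions and library sizes of the 12960 tested genes, with 200 genes changed between BHB and untreated. It recovered 49 of 67 genes changed by 1.5-fold, 56 of 67 changed by 2-fold and 62 of 66 changed by 3-fold. Of 177 calls, 10 were on genes that had not been changed. Among 33 simulated lists of 30 genes, camera called the list raised by 1.2-fold and 0 of the others. The simulated genes were drawn independently, so this does not test false calls on lists whose members move together. In the data, estimated correlations of called lists ran from -0.0661 (prostate markers) to 0.682 (interferon-stimulated genes). With the libraries' GC and length trend simulated, the corrected fit recovered 54 of 67, 61 of 67 and 63 of 66 genes, and 6 of its 184 calls were on unchanged genes. The fit without correction recovered 51, 61 and 63 genes of the same simulated data, with 4 of 179 calls on unchanged genes. The simulated dispersions were estimated with the trend still in the libraries, so this simulation cannot show what the correction gains. In the deposited data the correction gave 264 genes higher and 512 lower, against 87 and 192 without it. Alternatives were DESeq2 size factors, total counts only, DESeq2 1.42.0, limma-voom, no low-count filter, a minimum of 50 counts in 2 samples, a test against a fold change of 1.2, the replicate number as a block, leaving out each replicate, a prior count of 0.5, and the alternatives added after the data were examined (transcript rows and the GC and length correction). Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.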

Results

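The effect of the ketone body beta-hydroxybutyrate on gene expression was measured by RNA-seq in PPS-ICBR cells, a castration- and immunotherapy-resistant mouse prostate cancer line. The 2 untreated samples held 26984713 and 24750740 gene-level counts and the 2 samples given 3 mM BHB for 18 h held 27872163 and 27942749. Between 15670 and 15843 genes had at least 1 count in a sample. The first principal component of log2 CPM separated the groups and held 49.2% of the variance. The second, with 28.8%, separated mainly the 2 untreated samples. Counts of the untreated pair differed by 16.4 times sampling noise (chi-square per degree of freedom over genes), against 4.7 for the BHB pair and 11.4 to 22.2 for pairs across groups. No pair agreed within sampling noise.

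The genes knocked out in this line still had reads in every sample. Pten stood at 41.7 ± 3.4 CPM in untreated and 43.7 ± 0.9 CPM in BHB samples (SD, n = 2 per group here and below). Trp53 stood at 8.31 ± 0.58 and 9.9 ± 0.24 CPM, and Smad4 at 20.1 ± 0.79 and 20.7 ± 1.8 CPM. None of the 3 passed the test (edgeR quasi-likelihood, adjusted p = 0.812, 0.41 and 0.916). No sample with intact copies was analysed here, so these values check no label.

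The comparison of BHB with untreated cells asked which transcripts change when the ketone body is supplied. Among called genes with a mean count of at least 50, the largest rise was that of Abca1, the cholesterol and phospholipid exporter, which went from 1.09 ± 0.6 to 11.1 ± 1.1 CPM, a 10-fold change (log2 fold change 3.33 ± 0.24 SE, edgeR adjusted p = 1.33e-06, and 4.07 without untreated replicate 1 and 2.87 without untreated replicate 2). Dhrs3, a retinaldehyde reductase, rose 5.76-fold (adjusted p = 3.07e-08) and Calcb, which encodes a calcitonin gene-related peptide, rose 5.47-fold (adjusted p = 3.07e-08). Angptl4, a secreted inhibitor of lipoprotein lipase, had the smallest p of all genes and rose from 56.2 ± 1.5 to 223 ± 0.58 CPM (3.98-fold, adjusted p = 2.45e-09). Large falls in the same range of counts were those of Penk, the enkephalin precursor, from 27.9 ± 4 to 8.32 ± 1.7 CPM (log2 fold change -1.74 ± 0.14 SE, adjusted p = 5.17e-06), Olfr805, an olfactory receptor gene (-1.68 ± 0.25 SE, adjusted p = 0.00184), and Postn, which encodes the matrix protein periostin, from 42.9 ± 5.9 to 15.5 ± 0.33 CPM (-1.47 ± 0.11 SE, adjusted p = 2.13e-06). In total, 87 genes were higher and 192 lower with BHB among 12960 tested, and 46 of these 279 changed by 2-fold or more.

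**Figure D1:**
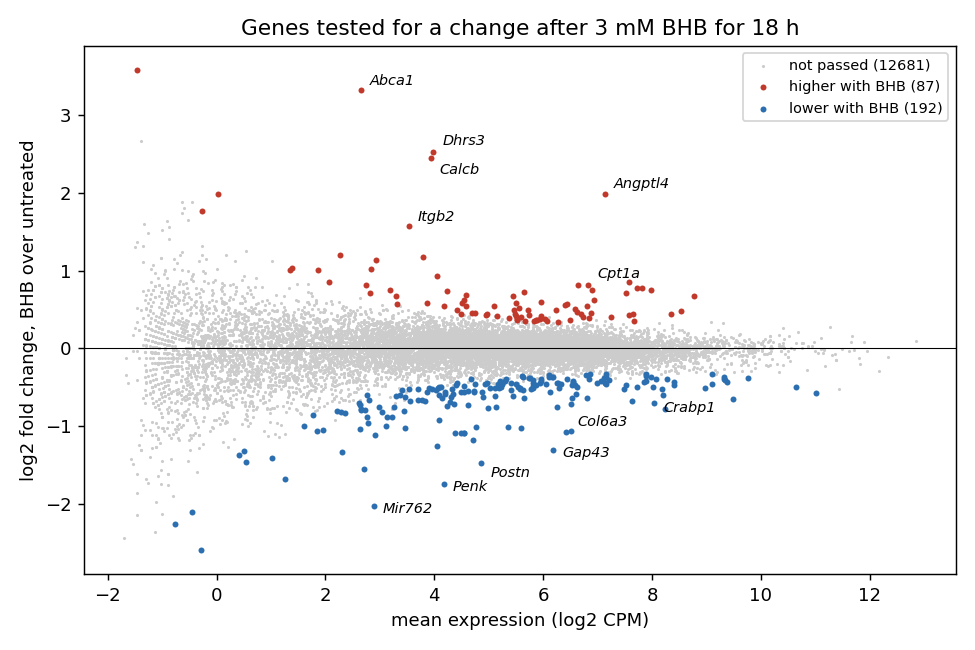
Each point is one of the 12960 tested genes, placed by its mean expression (log2 CPM, x axis) and its log2 fold change of BHB over untreated (y axis). The 87 genes called higher are red and the 192 called lower are blue, and Abca1 lies at 3.33 and Angptl4 at 1.99.

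The other large rises were in Itgb2, an integrin subunit of leukocytes (2.97-fold, from 5.72 ± 0.17 to 17 ± 0.15 CPM), Fbln7, a fibulin (2.3-fold), Edn1, which encodes endothelin (2.25-fold, from 8.39 ± 1.4 to 18.9 ± 0.43 CPM), Acot2, a mitochondrial acyl-CoA thioesterase (2.2-fold), the kinase gene Dapk2 (2.04-fold), the mitochondrial coenzyme A carrier Slc25a42 (2.01-fold), the cyclic GMP phosphodiesterase Pde9a (2-fold) and Lipe, the hormone-sensitive lipase (1.9-fold, from 11.3 ± 0.83 to 21.6 ± 1 CPM). Dapk2 and Slc25a42 were near the low end of expression, at 1.66 ± 0.1 and 1.63 ± 0.2 CPM in untreated cells, and passed with adjusted p = 0.0444 and 0.0379. Slc25a42 lost its call whichever sample was left out, Dapk2 without untreated replicate 1, untreated replicate 2 or BHB replicate 1, and Pde9a without untreated replicate 1 or BHB replicate 2. Among the falls, Gap43, a growth-cone protein of neurons, went from 103 ± 5.2 to 41.9 ± 4.4 CPM (log2 fold change -1.30 ± 0.09 SE, adjusted p = 1.33e-06). Ccbe1, a secreted factor of lymphatic growth, went from 23.3 ± 1.1 to 9.79 ± 1.2 CPM. The log2 fold changes were -1.41 for the guanine nucleotide exchange factor Mcf2l (not called without untreated replicate 2), -1.18 for the zinc finger gene Zfp771, -1.11 for the carboxypeptidase Cpa4 and -1.09 for Scand1 (-0.56 without untreated replicate 1). Rnaset2a and Rnaset2b, near-identical copies of a lysosomal ribonuclease gene, had the same counts in every sample (-1.09 each), so which copy fell is not known. Mir762 had the lowest value of this set (-2.03, 11.8 ± 5.8 to 2.9 ± 0.99 CPM, and -1.41 without untreated replicate 1), and it lies inside Bcl7c in the GRCm38.p6 gene table. Bcl7c, chosen after its value was seen, fell too (-0.45, adjusted p = 0.0248), so these reads cannot be assigned to the microRNA. Bcl7c lost its call without untreated replicate 1, BHB replicate 1 or BHB replicate 2.

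**Figure D2:**
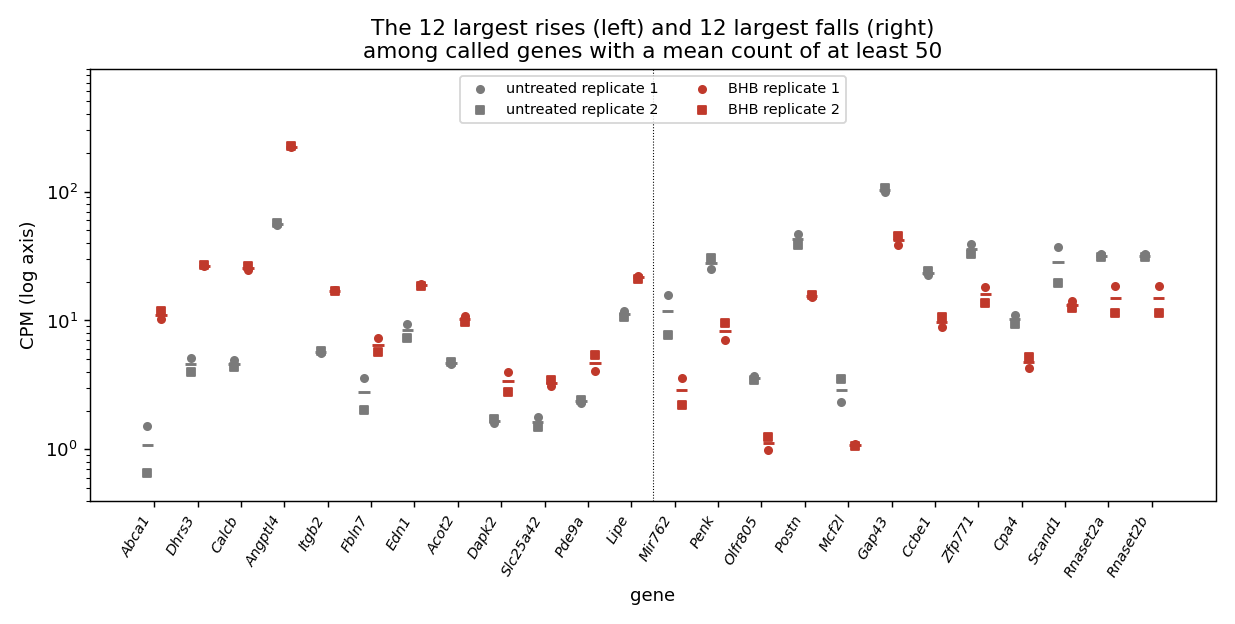
CPM (log axis) of the 12 largest rises and 12 largest falls in each sample, with circles for replicate 1, squares for replicate 2 and a line at the mean of each group. In all 24 genes both BHB samples lie on the same side of both untreated samples, which the choice of genes required.

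A fit with 1 sample left out took its within-group spread only from the group that kept 2. Without a BHB sample that was the untreated pair (16.4 times sampling noise), without an untreated sample the BHB pair (4.7). A call lost or gained in such fits is therefore not by itself a changed effect. S100a4 lost its call without BHB replicate 1 or BHB replicate 2 at log2 fold changes within -0.396 to -0.38. Cmpk2 ranged from -0.633 to -0.258. The number of calls differed between these fits. It was 35 higher and 86 lower without BHB replicate 1, 52 and 108 without BHB replicate 2, 132 and 264 without untreated replicate 1, and 525 and 685 without untreated replicate 2, and removing each library's GC and length trend gave 264 higher and 512 lower, with all 87 and 192 of the original calls among them.

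Camera at its preset correlation called the list of fatty acid oxidation genes and targets of the lipid-sensing PPAR receptors higher with BHB. Of 33 measured members, 9 rose, 2 fell and 22 did not pass (11 rose and 2 fell when adjusted over the list alone), and 29 had a positive sign. Besides Angptl4 and Acot2, the risen genes were Cpt1a, which commits long-chain fatty acids to mitochondrial import (82 ± 12 to 145 ± 2.3 CPM, adjusted p = 0.000224), the lipid droplet protein Plin2 (338 ± 18 to 538 ± 3.5 CPM, adjusted p = 0.000333), the acylcarnitine carrier Slc25a20 (1.59-fold), and the oxidation enzymes Acadl (1.48-fold), Acaa2 (1.42-fold), Eci2 (1.41-fold) and Etfb (1.33-fold). The fatty acid-binding proteins Fabp4 (30.8 ± 2.3 to 18.6 ± 2.3 CPM, adjusted p = 0.00246) and Fabp5 (248 ± 0.13 to 175 ± 9.6 CPM, adjusted p = 0.00356) fell. The list median was 0.22 and camera gave adjusted p = 9.99e-08. The median difference of members was -0.036 log2 units for untreated replicate 1 over replicate 2, and 0.031 for BHB replicate 1 over replicate 2. Whichever sample was left out, the list median lay between 0.18 and 0.22. With an estimated correlation the p was 0.0507 before and 0.777 after adjustment. Without BHB replicate 1 the risen genes numbered 6, with Acaa2, Eci2, Etfb and Fabp5 not passing, and without BHB replicate 2 Eci2 and Etfb did not pass. Against a fold change of 1.2, 5 members rose and 1 fell.

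The list of extracellular matrix genes was called lower with BHB by camera at its preset correlation. Of 24 measured members, 6 fell, none rose and 18 did not pass (12 fell when adjusted over the list alone). The largest falls were those of Postn and the collagen gene Col6a3 (116 ± 27 to 55.3 ± 1.9 CPM, log2 fold change -1.08 ± 0.12 SE, adjusted p = 0.000138). Fbln2 (-0.68), Col3a1 (590 ± 96 to 413 ± 23 CPM, -0.52), Col18a1 (-0.48) and the laminin gene Lamc2 (-0.43) also fell. The list median was -0.31 (camera adjusted p = 1.43e-06, and adjusted p = 0.777 with an estimated correlation). The untreated samples differed in these same genes, with a median of 0.34 log2 units for untreated replicate 1 over replicate 2. Without untreated replicate 1 the list median was -0.11 with 6 members falling and camera adjusted p = 0.0105, Col3a1 had a value of -0.34 and Col18a1 of -0.28, and without untreated replicate 2 the median was -0.42 with 15 falling. Without BHB replicate 1 only Postn and Col6a3 kept their calls, and without BHB replicate 2 Lamc2 and Col18a1 lost theirs. Fbln2 also lost its call without untreated replicate 1. The members that fell numbered 3 with no low-count filter and 2 against a fold change of 1.2. Among genes of the mesenchymal state, 4 of 30 fell and 1 rose (9 and 1 over the list alone). Mmp3, a matrix metalloproteinase, fell from 30.4 ± 2.5 to 14.3 ± 0.45 CPM (adjusted p = 4.09e-05), Thbs1, S100a4 and Serpine1 had log2 fold changes of -0.50, -0.39 and -0.41, and Ctgf rose 1.39-fold. Of these 5 genes, Mmp3 kept its call whichever sample was left out. Without BHB replicate 1 the other genes of the list lost theirs, as did Thbs1, S100a4 and Ctgf without BHB replicate 2 and Serpine1 without untreated replicate 1. Camera did not call that list (adjusted p = 0.0693), except without untreated replicate 2 (adjusted p = 0.0117), where 11 members fell, and its median of -0.09 turned to 0.02 without untreated replicate 1. The GC and length correction gave 8 falling mesenchymal genes, no low-count filter 2, and a test against a fold change of 1.2 gave 1 with none rising.

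For interferon-stimulated genes camera at its preset correlation called the list lower with BHB. Of 49 measured members, 6 fell, none rose and 43 did not pass over all genes, while 17 fell and 2 rose when adjusted over the list alone. The antiviral genes Oas3 (115 ± 2 to 81.8 ± 2.7 CPM, adjusted p = 0.00391) and Oas1g (50.1 ± 10 to 34.5 ± 1.3 CPM, adjusted p = 0.0258) fell most by p, and Cmpk2 (-0.46), Gbp3 (-0.36), the transcription factor Irf7 (-0.36) and Samd9l (-0.34) followed. The list median was -0.22 (camera adjusted p = 7.28e-07, and adjusted p = 0.777 with an estimated correlation). Here untreated replicate 2 was the higher of the untreated pair, by a median of 0.24 log2 units (replicate 1 minus replicate 2, -0.24). Without untreated replicate 2 the list median was -0.08 with camera adjusted p = 0.07, and Oas1g and Cmpk2 had values of -0.30 and -0.26. With untreated replicate 1 left out the list median was -0.33 with 26 members falling, and without BHB replicate 1 no member passed in edgeR and the median was -0.24. Without BHB replicate 2, Oas3 and Oas1g alone kept their calls among the 6, and 1 other member rose, as 1 did without untreated replicate 2. The number that fell depended on the settings: it was 17, with 1 rising, after the GC and length correction, 2 at a minimum of 50 counts, 1 with no low-count filter or with transcript rows summed, and 0 against a fold change of 1.2. No gene of MHC class I antigen presentation passed the edgeR test among 22 measured, where 7 had lower values at an unadjusted p under 0.05 and both DESeq2 and limma-voom called 1 lower (2 fell when adjusted over the list alone). H2-Q4 and Tap1 had log2 fold changes of -0.32 each (adjusted p = 0.0508 and 0.0637), H2-K1, H2-D1 and B2m had values of -0.06, -0.10 and 0.03. Camera called the list lower (median -0.10, adjusted p = 0.0111, and adjusted p = 0.777 with an estimated correlation), and the call was lost without untreated replicate 2 (adjusted p = 0.361), BHB replicate 1 (0.0532) or BHB replicate 2 (0.0633). In that list 4 members fell without untreated replicate 1 and with the GC and length correction, and 2 rose and 2 fell without untreated replicate 2, with H2-Q4 and Tap1 among those that fell each time. Cd274, the immune checkpoint ligand PD-L1, stood at 6.1 ± 0.19 and 4.79 ± 0.72 CPM (adjusted p = 0.356).

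**Figure D3:**
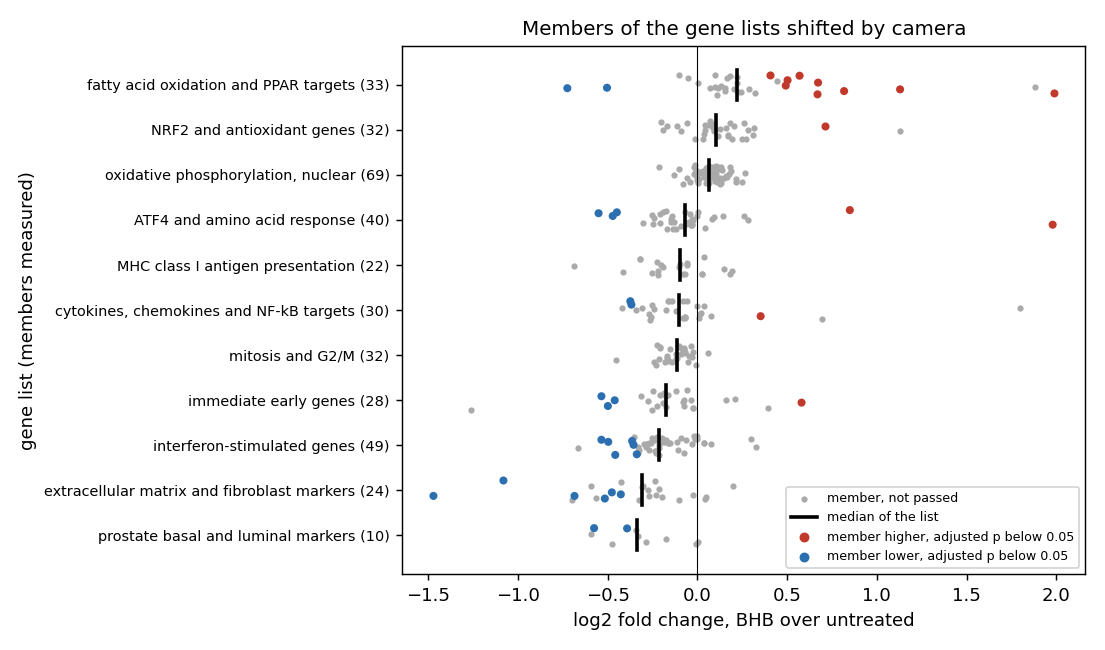
Log2 fold change of BHB over untreated (x axis) for each measured member of the 11 gene lists called by camera (y axis), with called members in red or blue and the list median as a black bar. The medians run from 0.22 for fatty acid oxidation and PPAR targets to -0.34 for prostate basal and luminal markers.

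Camera called 2 other lists higher. Antioxidant genes of the NRF2 response had a median of 0.11 over 32 members (adjusted p = 0.00283, and adjusted p = 0.777 with an estimated correlation). Of these, 1 rose, the haem-degrading enzyme Hmox1, from 139 ± 1.2 to 228 ± 2.2 CPM (adjusted p = 0.000138). Over the list alone 2 rose, without untreated replicate 2 the number was 7 with 1 falling, without BHB replicate 2, in DESeq2 and with total counts only it was 2, the GC and length correction gave 4 with 1 falling, and the call on the list was lost without untreated replicate 1 (adjusted p = 0.14, median 0.06). Nuclear genes of oxidative phosphorylation had a median of 0.06 over 69 members (adjusted p = 0.0193, and adjusted p = 0.787 with an estimated correlation). None of them passed in edgeR, DESeq2 or limma-voom, and 4 were higher and 1 lower at an unadjusted p under 0.05 (0 when adjusted over the list alone). That call was lost without untreated replicate 1 (adjusted p = 0.635, median 0.00 and camera direction down), without BHB replicate 1 (0.127) and with the GC and length correction (0.255, 1 member falling), and without untreated replicate 2 the median was 0.17 with 19 members rising.

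Another 5 lists were called lower, each with adjusted p = 0.777 under an estimated correlation. The prostate basal and luminal markers had a median of -0.34 over 10 members (adjusted p = 0.00226), of which the luminal keratins Krt8 (-0.57 ± 0.09 SE) and Krt18 (-0.39 ± 0.09 SE) fell (3 over the list alone). Both lost their calls without BHB replicate 1, and Krt18 without BHB replicate 2. The falling markers numbered 4 with the GC and length correction and 1 with no low-count filter or against a fold change of 1.2. Both keratins also belong to the epithelial list, in which the desmosomal gene Pkp3 fell (-0.80) and the claudin gene Cldn4 rose (0.43), and which camera did not call (15 members, 1 rising and 4 falling over the list alone, adjusted p = 0.079) except with no low-count filter (adjusted p = 0.0237). No epithelial gene rose with no filter, at a minimum of 50 counts, with rows summed or against a fold change of 1.2, where 1 fell. Pkp3 lost its call without BHB replicate 1, and Cldn4 without untreated replicate 1, untreated replicate 2 or BHB replicate 1. Immediate early genes had a median of -0.17 over 28 members (adjusted p = 0.00419), of which Jund, Ier5 and Dusp5 fell and Klf10 rose 1.5-fold (6 fell and 2 rose over the list alone). No member fell and 3 rose without untreated replicate 1, 6 fell without untreated replicate 2, and no member passed without BHB replicate 2 or against a fold change of 1.2. With total counts only or limma-voom 1 member fell, and with no low-count filter, a minimum of 50 counts or rows summed none did. With the GC and length correction 2 immediate early genes rose. Dusp5 also lost its call without BHB replicate 1. Mitotic genes had a median of -0.11 over 32 members (adjusted p = 0.000808), and no member passed in edgeR or limma-voom. DESeq2 called 1 lower, as did edgeR when adjusted over the list alone, 7 were lower at an unadjusted p under 0.05, Mki67 had a log2 fold change of -0.46 (adjusted p = 0.0553, and -0.23 without untreated replicate 1), and the list call was lost without BHB replicate 1 (adjusted p = 0.288). Mitotic genes that fell numbered 3 without untreated replicate 2 or with the GC and length correction and 1 without BHB replicate 2, with Mki67 among them each time. Cytokines and NF-kB targets (30 members, median -0.10, adjusted p = 0.0489) held Csf1 (286 ± 1.8 to 221 ± 2.8 CPM) and Spp1 (-0.37), which fell, and Ccl2, which rose 1.28-fold (4 fell and 2 rose over the list alone). These 3 genes lost their calls without BHB replicate 1 or BHB replicate 2. The list median was -0.15 without untreated replicate 1, -0.18 without BHB replicate 2 and -0.04 without BHB replicate 1. The list call was lost without untreated replicate 2 (adjusted p = 0.361), without BHB replicate 1 (0.606) or with no low-count filter (0.124), where no member passed. Against a fold change of 1.2 none passed either, 1 cytokine gene fell and none rose at a minimum of 50 counts or with rows summed, 1 fell with DESeq2 size factors, and 4 fell with the GC and length correction. Genes of the ATF4 amino acid response (40 members, median -0.07, adjusted p = 0.0489) held Nupr1 (1.8-fold) and the hormone gene Fgf21 (0.374 ± 0.11 to 1.48 ± 0.27 CPM, near the detection floor with 8 and 11 counts in the untreated samples), which rose, and Chac1, Stc2 and Cebpb, which fell (5 fell and 3 rose over the list alone). Without BHB replicate 2, Nupr1 alone of these kept its call, without BHB replicate 1 Chac1 and Stc2 lost theirs, and without untreated replicate 1 Fgf21 and Cebpb did. The list call was lost without untreated replicate 2 (adjusted p = 0.209), BHB replicate 1 (0.338) or BHB replicate 2 (0.209) and with total counts only (0.0503). Without untreated replicate 2, 4 members rose and 5 fell, with the GC and length correction 6 fell, with no low-count filter 1 fell, in DESeq2 and at a minimum of 50 counts 1 rose, and against a fold change of 1.2 1 rose and none fell.

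Genes of ketone body metabolism and transport did not pass the edgeR test in any of 9 measured members (2 higher and 1 lower at an unadjusted p under 0.05, DESeq2 called 1 lower and limma-voom none). With the GC and length correction or without untreated replicate 1, 1 member fell, and without untreated replicate 2, 2 rose and 1 fell, which was Oxct1 each time. Oxct1, which activates ketone bodies for oxidation, stood at 492 ± 33 CPM in untreated and 400 ± 18 CPM in BHB samples (log2 fold change -0.30 ± 0.09 SE, adjusted p = 0.0893, and 0.028 adjusted over the list alone). The transporter gene Slc16a1 was at 85.1 ± 0.58 and 85.4 ± 0.82 CPM, and Bdh1, which oxidises BHB, was near the detection floor at 0.448 ± 0.0069 and 0.392 ± 0.15 CPM. Hmgcs2 had no count in any sample, and Hcar2 and Nlrp3 had too few counts to be tested. Of 17 measured genes reported elsewhere to rise with histone deacetylase inhibitors or BHB, Clu (1.71-fold) and Tgm2 (1.35-fold) rose and Cpa4 fell (5 rose and 4 fell over the list alone). Tgm2 lost its call without BHB replicate 1 or BHB replicate 2. In that list 4 rose and 4 fell without untreated replicate 2, 2 fell without untreated replicate 1 or in DESeq2, 3 fell with the GC and length correction, and 1 rose against a fold change of 1.2. The median of this list was -0.16 and camera did not call it (adjusted p = 0.819). The median turned to 0.025 without untreated replicate 1, with camera direction up (adjusted p = 0.916), and at a minimum of 50 counts it was -0.08. In it, the metallothionein gene Mt1 had a log2 fold change of 0.28 (adjusted p = 0.0979), Mt2 0.21 (0.256), Foxo3 -0.16 (0.552) and Cdkn1a -0.36 (0.25). Mt1 was called higher without untreated replicate 1, without untreated replicate 2 and with the GC and length correction. Foxo3 was called lower without untreated replicate 2 (-0.33) and had a value of 0.025 without untreated replicate 1, and Cdkn1a had values of -0.17 without untreated replicate 1 and -0.22 without BHB replicate 1. Hdac1 had a value of -0.09 (0.674) and the androgen receptor gene Ar a value of -0.23 (0.576), which ranged from -0.40 without untreated replicate 2 to -0.02 without untreated replicate 1 and was -0.38 without BHB replicate 1 and -0.10 without BHB replicate 2.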

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

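The GC and length correction and the treatments of transcript rows were chosen after the data were examined, and the other alternatives before. The numbers of higher (87) and lower (192) genes stayed within 1.5 times under DESeq2 size factors, total counts only, DESeq2, limma-voom, a minimum of 50 counts, summed rows and separate rows (63 to 101 higher, 152 to 196 lower). Fewer of the same genes were shared. Of the 87, from 60 (summed rows) to 87 (total counts only) were called again, and of the 192 from 138 (summed rows) to 187 (separate rows). DESeq2 shared 71 and 157. Without a low-count filter, with 17381 genes tested, 43 and 82 were called. Against a fold change of 1.2, 23 and 43 passed. The GC and length correction gave 264 and 512. Leaving out single replicates gave 35 to 525 higher and 86 to 685 lower, with 1 residual degree of freedom and the lone sample of a group assumed to vary like the other group. Without BHB replicate 1, 34 of the 87 and 74 of the 192 genes kept their call, and without untreated replicate 2, 77 and 183 did. Falls made up 68.8% of calls in the comparison as reported and 56.6% without untreated replicate 2. For the calls that moved, the cause was not tested beyond the fewer samples or the other number of genes.

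The replicate numbers shared by the groups give 2 pairs, and deviations of same-numbered samples correlated by 0.0459 over all genes and 0.135 over genes with log2 CPM over 3. The titles write Cell Line with the same numbers in both groups, but no label says that equal numbers share a culture. With only 2 pairs and that left open, they were not taken as pairs. The comparison as reported therefore ignores a pairing if there was one. With the replicate block, 196 genes were higher and 380 lower, all original calls among them, and 3 lists were up and 6 down, without the cytokine (adjusted p = 0.0778) and ATF4 (0.076) lists. Interferon-stimulated genes then numbered 10 falling and 1 rising, and 7 mesenchymal genes fell. The replicate block with the GC and length correction gave 318 and 589.

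The lists called up (3) and down (8) were 0 and 0 with an estimated correlation, 0 and 1 with fry (the epithelial list, adjusted p = 0.0119), and 1 to 4 up and 5 to 13 down when a replicate was left out. Of 87 called genes named here, 44 kept their call without BHB replicate 1, 50 without BHB replicate 2, 73 without untreated replicate 1 and 83 without untreated replicate 2, and none with a value changed sign under the alternatives run on single genes (86 had a value with DESeq2 and at the minimum of 50 counts). Against a fold change of 1.2, 36 of the 87 kept their call, with no low-count filter 53, with rows summed 69, and at a minimum of 50 counts 73. Under the other settings with all 4 samples, 80 or more did. Separate transcript rows were not compared gene by gene. Among named genes not called, Slc16a1 (0.01 as reported) turned to -0.00146 at a minimum of 50 counts, -0.00241 with the GC and length correction and -0.0024 with the replicate block added, and B2m to -0.0585 with the GC and length correction and -0.0578 with the block added. With a replicate left out, Pten ranged from -0.0149 to 0.154, Smad4 from -0.053 to 0.125, Bdh1 from -0.641 to 0.15, Slc16a1 from -0.00412 to 0.0132, Foxo3 from -0.325 to 0.025, Srebf1 from -0.115 to 0.033 and B2m from -0.00578 to 0.0549. At this depth 11103 genes were too low to test.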

Other observations

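The GC and length correction, its tests on the lists, tests of single untreated replicates and the test of the deacetylase hypothesis were chosen after the results were seen. The share of single-exon genes among the falls was itself noticed in the results, and the bounds of the GC, length and genomic DNA tests on it were set after that, before the values of those tests were seen. Genes in this first paragraph were chosen after their values were seen. Outside the fixed lists, 4 more genes of lipid handling were among those that rose: the triglyceride lipase Pnpla2 (38.5 ± 0.27 to 51.5 ± 2.4 CPM, edgeR adjusted p = 0.0176), the malonyl-CoA decarboxylase Mlycd (1.5-fold, adjusted p = 0.0126), the enoyl-CoA isomerase Ech1 (1.35-fold, adjusted p = 0.0171) and the thioesterase Acot13 (1.47-fold, adjusted p = 0.0125). Srebf1, a target of the sterol receptors that also act on Abca1, had a log2 fold change of -0.04 (adjusted p = 0.876). Besides Dhrs3, the retinoid receptor gene Rarb rose (49.3 ± 5.4 to 74.5 ± 4.1 CPM, adjusted p = 0.00273), while the retinoic acid-binding protein Crabp1 fell (327 ± 39 to 201 ± 20 CPM, adjusted p = 0.00116). Among the genes that fell were 5 for secreted members of families that include antagonists of BMP or WNT signals. Their log2 fold changes were -1.07 for Grem1 (124 ± 0.71 to 59.2 ± 3.6 CPM), -0.81 for Nog, -0.51 for Nbl1, -0.65 for Dkk2 (882 ± 14 to 562 ± 37 CPM) and -0.42 for Dkk3. Not every member of these families is an antagonist. Without BHB replicate 1, Pnpla2, Mlycd, Ech1, Acot13, Dkk2 and Dkk3 lost their calls, and without BHB replicate 2 Pnpla2, Mlycd, Ech1, Nbl1 and Dkk3 did. Other genes of these kinds were not counted, and no enrichment was tested.

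The remaining fixed lists were not called by camera in the comparison as reported. Called members were Acsl4 (1.35-fold) among 19 fatty acid synthesis genes (adjusted p = 0.424), Pmepa1 (1.68-fold) among 16 androgen receptor genes (adjusted p = 0.329), Adm (1.38-fold) and Stc2 (-0.47) among 30 hypoxia genes (adjusted p = 0.206), Xbp1 (-0.37) among 23 genes of the unfolded protein response (adjusted p = 0.0674), Hspb1 (-0.68) among 20 heat shock genes (adjusted p = 0.829, median 0.05 and mean -0.01), Irs1 (-0.49) among 26 FOXO and AKT-feedback genes (adjusted p = 0.158) and Sox2 (-0.39) among 7 neuroendocrine markers (adjusted p = 0.532, median 0.04, mean -0.03 and camera direction down). Without BHB replicate 1 or BHB replicate 2, Acsl4, Adm, Stc2, Xbp1, Irs1 and Sox2 lost their calls, the last of them and Irs1 also without untreated replicate 1. Against a fold change of 1.2 these 6 genes lost their calls too, as did Stc2, Xbp1, Irs1 and Sox2 with no low-count filter, Stc2, Irs1 and Sox2 with rows summed, Irs1 and Sox2 with total counts only, and Irs1 in DESeq2, limma-voom and at a minimum of 50 counts. The heat shock median turned to -0.01 without untreated replicate 1. The neuroendocrine median turned to -0.11 without untreated replicate 1, -0.12 without BHB replicate 2, -0.09 in DESeq2 and with no low-count filter, and -0.08 at a minimum of 50 counts. Over the list alone, 2 fatty acid synthesis genes rose, 1 FOXO gene rose and 1 fell, and in the other lists named so far the numbers were as over all genes. No member passed in edgeR in the lists of cholesterol synthesis (27 measured, 4 up at an unadjusted p under 0.05, camera adjusted p = 0.449), glycolysis (24, 3 down, 0.11), the TCA cycle (24, 1 down, 0.443), S phase (34, 1 up and 1 down, 0.304), MYC targets (34, 1 down, 0.158), p53 targets (23, 3 up and 3 down, 0.741), histone deacetylases and sirtuins (18, 1 up, 0.741), checkpoint ligands (13, 1 up and 1 down, 0.329), replication-dependent histones (16, 1 up and 5 down, 0.0674), autophagy and lysosome (35, 8 up and 2 down, 0.0634) and ribosomal proteins (79, 0, 0.249). Adjusted over the list alone, 2 glycolysis genes fell, 3 p53 targets rose and 1 fell, 1 histone gene rose and 2 fell, and in the other 8 lists the number was 0. In these lists DESeq2 called 2 glycolysis genes lower and 1 histone gene higher, and limma-voom called none. Some of these lists were called under other settings. Without untreated replicate 1 camera called MYC targets (adjusted p = 0.00816), S phase (0.0256), the unfolded protein response (0.0132), histones (0.0284) and ribosomal proteins (0.000312) lower, while without untreated replicate 2 ribosomal proteins were called higher (1.35e-08, 25 rising) and hypoxia genes lower (0.0488, 5 falling). Histones were also called lower without BHB replicate 1 (0.000867) and with the GC and length correction (0.0467), as was the unfolded protein response with that correction (0.0235, 4 falling). Autophagy genes were called higher with the correction (0.0373, 4 rising) and without BHB replicate 2 (0.0164), and 3 rose without untreated replicate 1 and 8 without untreated replicate 2. In the other 9 of these 11 lists with no called member, 0 to 3 members rose and 0 to 3 fell under the other settings. Of 24 immune and 13 endothelial markers only 2 each had enough counts to be tested, and none passed in edgeR, also without adjustment.

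Single-exon genes made up 13% of the falls (25 of 192), 3.45% of the rises and 4.45% of uncalled genes (Fisher's exact p = 2.29e-06 for falls against uncalled, two-sided). Fisher's test here and below takes genes as independent. Once the GC and length trend of each library was removed, the share was 7.65% of 510 falls against 4.51% of uncalled genes (Fisher's exact p = 0.00238). This argues against that trend as the whole cause. All 192 falls stayed called, the 25 single-exon genes among them, so the lower share came with added falls and not with lost ones. The shares below also depend on how many genes each fit called. Genomic DNA in the untreated libraries would also raise silent genes, yet the 11103 genes too low to test summed to nearly the same CPM in both groups (log2 ratio -0.0724, from -0.15 to 0.01 over pairs of samples). That set was chosen on the same counts, and a silent gene raised past the filter in both untreated samples would have left it. The sums therefore speak only to a rise too small to carry genes past the filter. Without untreated replicate 1 the share was 6.84% of falls against 4.54% (Fisher's exact p = 0.0983), so a peculiarity of that library and an effect of BHB cannot be told apart with a single remaining untreated sample. The share was 6.88% against 4.59% of uncalled genes without untreated replicate 2, so the drop was not particular to leaving out untreated replicate 1. It was 24.4% against 4.44% without BHB replicate 1.

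The fall of the extracellular matrix list may rest in part on untreated replicate 1, whose counts rose with transcript length relative to untreated replicate 2 (Spearman's rho 0.37 across genes, which are not independent replicates). Removing the GC and length trend left the list median at -0.259 with camera adjusted p = 1.01e-05, which argues against that trend as the whole cause. Camera still called the list without untreated replicate 1 (median -0.108, adjusted p = 0.0105), a value that rests on a single untreated sample. Against untreated replicate 2 alone, a test and an interval requirement set after its value was seen, 62.5% of the 24 members were lower in both BHB samples (exact 95% interval 40.6 to 81.2, counting error only), against 37.5% of all genes. That interval leaves the share of the fall due to untreated replicate 1 open, so for the list as a whole that library and an effect of BHB cannot be told apart.

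For the interferon-stimulated list the library in question is untreated replicate 2. The GC and length correction left the median at -0.239 with camera adjusted p = 2.22e-07, which argues against that trend. Against untreated replicate 1 alone, under the same later requirement, 63.3% of the 49 members were lower in both BHB samples (exact 95% interval 48.3 to 76.6, counting error only), against 39.7% of all genes. The members are not independent (estimated correlation 0.682), so this interval is too narrow. That interval spans the bound of the test, so higher interferon-stimulated expression in untreated replicate 2 and a fall with BHB cannot be told apart for the list as a whole. The 6 members called in the comparison as reported had log2 fold changes of -0.258 or lower whichever sample was left out. These are the members with the smallest p, so their values do not speak for the list.

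A hypothesis for the action of BHB is inhibition of histone deacetylases, which would be expected to raise the list of genes reported to respond to such inhibitors. That list had a median of -0.161 with 2 members rising and 1 falling, and the members went both ways. The test asked for a positive median with a camera call up, or for a negative median with fewer members rising than falling. Neither was met, so the test does not decide. Without untreated replicate 1 the median turned to 0.025. Whether BHB acts on the fatty acid oxidation genes through PPAR receptors was not tested.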
